A study of Mus musculus with 12 samples.

How the data were processed

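Gene expression was measured in the whole pancreas of wild type mice and of mice lacking Mist1, after injections of saline or of caerulein, on 12 Affymetrix mouse arrays, 1 per pancreas. Per the labels, the mice were males of 2 to 4 months, the injections were given hourly for 4 hours, and about 10 µg of total RNA per pancreas was labelled. Each of the 4 groups held 3 pancreata, which the series' design text calls biological replicates. Samples were placed in groups by the genotype and injection in their titles, and no sample was left out.

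The deposited values were linear signal intensities, 1 per probe set and array, with 1 decimal and all above 0. Their 2% trimmed means lay between 151.08 and 151.37 on the 12 arrays, so the arrays had been scaled to a common mean. The software that summarised the probes, the scaling target and any detection calls are not given in the sources used here, so signal over background could not be read from the values. The array medians lay between 70.6 and 90.15, a range of 1.28-fold. They were within the limit fixed before the data were examined, and the deposited scaling was therefore kept. No pair of arrays held identical values. The number of arrays limits the precision of every value.

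The table held 22516 probe sets, of which 64 were controls. The platform annotation gave a single gene symbol to 20240 of the others, several symbols to 682 and none to 1530. No symbol changed when the annotation was updated through the gene identifiers of the reference gene table, whose assembly is GRCm38.p6. No gene was named from a probe set with several symbols.

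An offset of 18.7, the 20th percentile of all values, was added to each value before taking log2. Folds are therefore on the log2(value + 18.7) scale, which understates the change of dim genes. Control probe sets and probe sets whose mean log2 value lay at or below the 30th percentile of such means were left out, which left 15716 probe sets of 9481 named genes or of no single gene. A mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 8 residual and 5.75 prior degrees of freedom. Each of the 4 comparisons of groups, and the interaction of genotype and injection, was tested from both sides with limma's moderated test. The p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

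Gene lists were written down before the files were opened, with 633 gene symbols, of which 560 were matched to the annotation. The 30 lists were digestive enzymes and secreted acinar proteins, Reg family secreted stress proteins, acinar transcription factors, Mist1-dependent genes of earlier work, granule exocytosis machinery, calcium signalling and secretagogue receptors, ER chaperones and ER-associated degradation, the integrated stress response and amino acid response, heat shock response, immediate early genes, NF-kB targets with cytokines and chemokines, p53 targets, oxidative stress and metallothioneins, sterol biosynthesis, circadian clock, cell cycle, cell junctions and polarity, actin cytoskeleton and early epithelial injury, ribosomal proteins, ribosome biogenesis and nucleolus, oxidative phosphorylation, liver-type secreted proteins, and markers of duct cells, islet endocrine cells, fibroblasts with stellate cells and matrix, endothelium, adipocytes, neutrophils with macrophages, lymphocytes with antigen presentation, and red blood cells. A list needed at least 4 measured members. The hemoglobin list of red blood cells had fewer and was not tested, which left 29. A gene with several probe sets was represented by the one with the highest mean over the 12 arrays.

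Each list was compared with all other genes by camera in limma, with a preset correlation of 0.01 between genes, and its p-values were adjusted over the 29 lists within a comparison. Camera was also run with the correlation estimated from the data, and fry was run beside it. Fry results are not given below, and they differed from those of camera in both directions. With caerulein in wild type, oxidative stress and metallothioneins had fry adjusted p = 0.00114 and camera adjusted p = 0.0888. For Mist1KO against wild type after saline, ER chaperones and ER-associated degradation had fry adjusted p = 0.169 and camera adjusted p = 0.0401. Members past the threshold were counted with the adjustment over all probe sets and again adjusted over the list alone. Unless a sentence says otherwise, a member rose or fell when its p-value adjusted over all probe sets was under 0.05.

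The design, the tests, the lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison of groups, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose 3 arrays of one group all lay beyond the 3 of the other, leaving out predicted genes without a name. For the interaction it took 5 each way. It added up to 4 members of each list, by smallest adjusted p, Bhlha15 in every sample, and Atf3, Eif2ak3, Ern1 and Atf6 in all comparisons. Genes named outside it are marked as chosen after their values were seen. A gene that the rule took for the genotypes after saline is not reported here.

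The scripts were tested on simulated data made from the means and spreads of these arrays. For caerulein against saline in wild type, 49% of 100 probe sets changed by 1 on the log2 scale were recovered among the 15716, and 86% of 100 changed by 2. Of 140 calls there, 5 were of unchanged probe sets. No call was made in either comparison without simulated changes, and the shifted list was the only 1 of 29 lists called. The noise was drawn independently for each probe set. The simulation therefore cannot show how often the list test errs when genes are correlated.

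Alternatives were an offset smaller by a factor of 4 and no offset, quantile normalization, centring each array on its median, no filter and a filter at the 60th percentile, no intensity trend, only the 2 groups compared, the replicate number as a block, each array left out in turn, a threshold that also asks for a 2-fold change, the estimated correlation in camera, and the mean of all probe sets of a gene. The share of called genes on the chromosome of Bhlha15 was compared with that of the other chromosomes by Fisher's exact test, since a knockout made in another strain can carry that strain's alleles around the gene. RNA quality was read from the ratio of the 3′ to the 5′ control probe sets of Actb and Gapdh on each array, with that of the pyruvate carboxylase control added later, and array scale from 18 control probe sets of hybridisation spikes, transcripts added to every sample before hybridisation.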

Results

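The study set mice without Mist1 (Mist1KO) beside wild type mice, each after saline or after caerulein, to read the effects of caerulein on the Mist1KO pancreas. Mist1, encoded by Bhlha15, is a basic helix-loop-helix transcription factor of secretory cells, among them the enzyme-producing acinar cells of the pancreas. Caerulein is an analogue of cholecystokinin that drives enzyme secretion and, in repeated high doses, causes acute pancreatitis. There were 3 pancreata in each of the 4 groups, with 1 array per pancreas and 15716 probe sets tested. Changes below are log2 differences ± SE with n = 3 per group, and folds are on the log2(value + 18.7) scale.

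Bhlha15 was far dimmer on all 6 Mist1KO arrays than on the wild type arrays. With its brightest probe set the signal was 1601, 1619 and 1624.3 in wild type after saline, and 776.8, 729.5 and 838.5 in wild type after caerulein. It was 89.9, 95.9 and 106.8 in Mist1KO after saline, and 42.6, 38.3 and 79.4 in Mist1KO after caerulein. A further probe set had group means of 381.8, 212.2, 70.6 and 69.7 in the same order. The gene lies on chromosome 5, from 144190286 to 144194441 (GRCm38.p6). Where its probes lie relative to the deleted part is not given in the sources used here. After caerulein, Bhlha15 fell 2.04-fold in wild type (-1.03 ± 0.18, adjusted p = 0.000934). With the same probe set it also fell 1.66-fold in Mist1KO (-0.73 ± 0.18, adjusted p = 0.00764). With the further probe set the changes were -0.80 ± 0.17 in wild type (adjusted p = 0.00424) and -0.01 ± 0.17 in Mist1KO (adjusted p = 0.973).

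**Figure D1:**
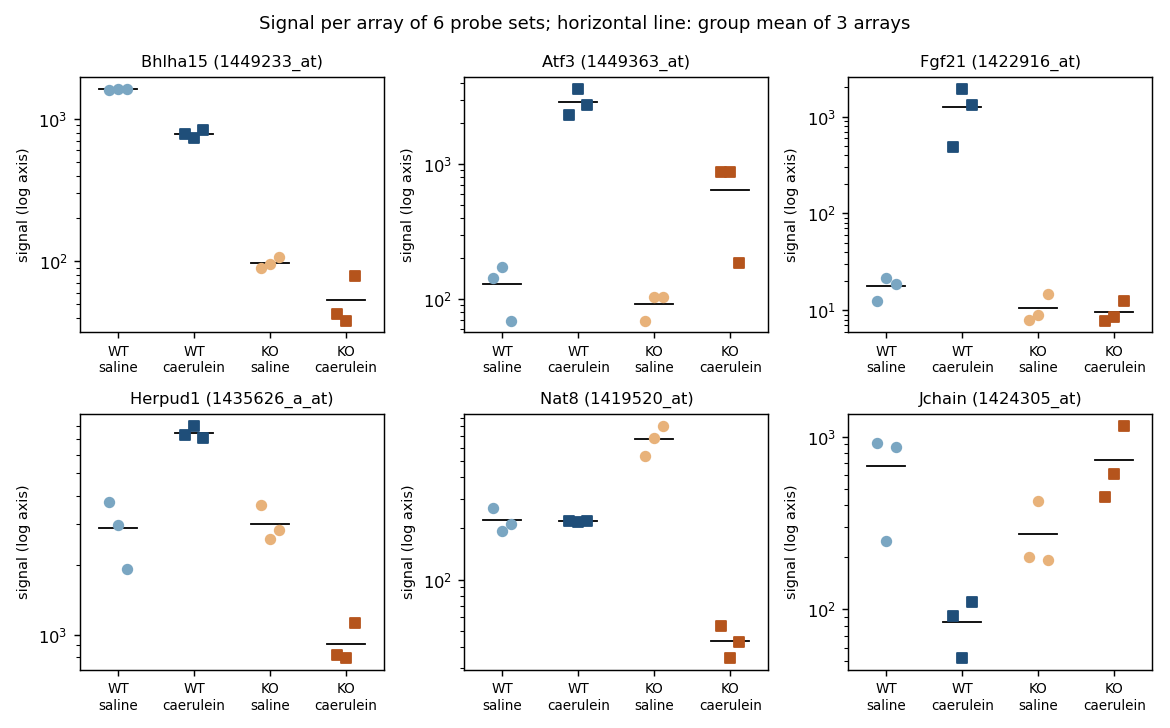
Signal of 6 probe sets on the 12 arrays, on log axes, with a horizontal line at the mean of the 3 arrays of each group. Fgf21 averaged 1246 in wild type after caerulein and 9.63 in Mist1KO after caerulein, and Nat8 averaged 675 in Mist1KO after saline and 43.4 after caerulein.

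The first principal component held 36.5% of the variance and separated the injections, with values from -41.8 to -29.78 after saline and from 23.91 to 52.12 after caerulein. The second held 23.3% and separated the genotypes, with values from 12.39 to 40 in wild type and from -30.07 to -26.87 in Mist1KO. Mist1KO caerulein replicate 3 lay at 28.87 on the first component, while the other arrays of its group lay at 47.43 and 52.12. Several array measures also differed between the groups. The hybridisation spikes had a geometric mean signal of 1260 ± 60 (SD, n = 3) in wild type saline, 1070 ± 324 in wild type caerulein, 915 ± 139 in Mist1KO saline and 446 ± 58.2 in Mist1KO caerulein. In the same order, the 50 brightest probe sets took 18%, 15.7%, 13.5% and 9.8% of the total signal, and the 3′ to 5′ ratio of Actb was 1.53, 1.35, 1.82 and 1.12. The 3′ to 5′ ratio of Gapdh lay between 0.963 and 1.13 in the group means, and that of the pyruvate carboxylase control was 1.82, 2.73, 2.36 and 3.26. The 18S ribosomal RNA control read 1120 on wild type saline replicate 3 and 282 or less on the other arrays.

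**Figure D2:**
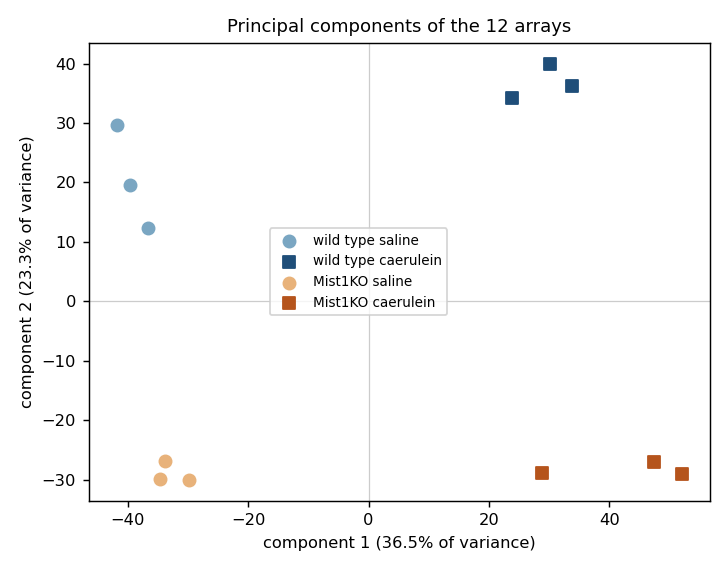
First and second principal components of the 12 arrays, 1 point per array, coloured by group. They hold 36.5% and 23.3% of the variance.

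Comparing Mist1KO with wild type after saline asks what the loss of Mist1 changed in the unstimulated pancreas. Among the largest falls were those of Egf, the epidermal growth factor, by 9.79-fold (-3.29 ± 0.18, adjusted p = 1.68e-07), Gjb1, the gap junction protein connexin 32, by 9.26-fold (adjusted p = 4.65e-05), and Atp2c2, a calcium pump of the secretory pathway, by 14.5-fold (adjusted p = 5.17e-07). Cblif, the gastric intrinsic factor that binds vitamin B12, was 50.9-fold higher (5.67 ± 0.26, adjusted p = 3.59e-08), with a mean signal of 1298 against 7.37 in wild type. Smarca1, a chromatin remodelling ATPase, was 29.8-fold higher (adjusted p = 5.84e-08).

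Other genes with large rises were Moxd1, a copper monooxygenase (14.7-fold), Hpgd, which inactivates prostaglandins (10.6-fold), Apcs, serum amyloid P (8.08-fold), Bex3 (7.31-fold) and Cldn18, a tight junction protein of stomach and lung (6.42-fold). A further probe set of Cldn18 pointed the same way without passing the threshold. The largest falls, besides those above, were of Bhlha15 itself (14.1-fold), Aass, an enzyme of lysine breakdown (9.2-fold), Fxyd6, a regulator of the sodium pump (8.46-fold), Reg3g, a secreted lectin (7.13-fold), and Qtrt1, which modifies transfer RNA (6.91-fold). All of these had adjusted p-values of 0.0056 or below. In each the 3 arrays of one genotype lay beyond the 3 of the other, as the rule for naming required. The same held for 1952 of all 1977 probe sets past the threshold.

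The list of Mist1-dependent genes of earlier work was lower in Mist1KO: 6 of 9 measured members fell, 1 rose and 2 did not pass (2 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.000406, adjusted p = 0.0813 with an estimated correlation). Whether earlier work picked any of them on arrays of these mice is not given in the sources used here, so the list is not independent evidence of its direction. Besides Atp2c2 and Gjb1, it holds Rab3d, a granule-associated GTPase (-1.88 ± 0.12, adjusted p = 4.27e-07), and Copz2, a coat protein of transport vesicles (-1.56 ± 0.16, adjusted p = 4.95e-05). The granule exocytosis machinery had 4 lower members of 21, Rab3d and Copz2 among them, and its list test gave adjusted p = 0.088. Among calcium signalling and secretagogue receptors, 2 of 17 fell, Atp2c2 and the calmodulin kinase Camk2b (-1.78 ± 0.23, adjusted p = 0.000333), with adjusted p = 0.103 for the list.

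As a list, digestive enzymes and secreted acinar proteins were lower (mean -0.61; camera adjusted p = 1.31e-07, adjusted p = 0.443 with an estimated correlation). Of 24 measured members, 5 fell and 19 did not pass, and 21 fell adjusted over the list alone. The count rested on the fit, with 17 fallen when Mist1KO caerulein replicate 3, outside this comparison, was left out. Ctrc, a chymotrypsin, fell by 2.11 ± 0.15 (adjusted p = 1.93e-06) and Prss3, a trypsinogen, changed by -1.81 ± 0.27 (adjusted p = 0.000922). The hybridisation spikes, which no tissue makes, fell by 0.48 on average in the same comparison. With quantile normalization the list's mean was -0.19 and its test did not pass (adjusted p = 0.265). The Reg family secreted stress proteins, lectins made by acinar cells, were lower too: 4 of 7 fell (5 adjusted over the list alone), led by Reg3g (-2.83 ± 0.56) and Reg3b (-1.07 ± 0.25, adjusted p = 0.0148). The calls of Reg3b, Reg3d and Reg2 each ended without several single arrays, with adjusted p-values of up to 0.0647, 0.0854 and 0.107. Camera gave adjusted p = 0.00209, adjusted p = 0.287 with an estimated correlation and adjusted p = 0.0899 after quantile normalization.

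In the integrated stress response and amino acid response, 9 of 29 measured members were lower, 1 was higher and 19 did not pass (12 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00276, adjusted p = 0.324 with an estimated correlation). Psat1, of serine synthesis, fell by 1.69 ± 0.23 (adjusted p = 0.000545) and Asns, asparagine synthetase, by 0.82 ± 0.12 (adjusted p = 0.00065). Higher as lists were oxidative phosphorylation, with 8 of 28 higher and none lower (10 adjusted over the list alone; adjusted p = 0.000326, adjusted p = 0.281 with an estimated correlation), and ribosome biogenesis and nucleolus, with 6 of 19 higher and none lower (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.00113, adjusted p = 0.159 with an estimated correlation). Examples were Uqcrb of complex III (0.73 ± 0.12, adjusted p = 0.00205) and Npm1, a nucleolar chaperone (1.05 ± 0.14, adjusted p = 0.000382).

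A further 6 lists passed with camera adjusted p-values between 0.0371 and 0.0466, and with an estimated correlation their adjusted p-values lay between 0.278 and 0.572. After quantile normalization none of the 6 passed (camera adjusted p from 0.064 to 0.24). Of the ER chaperones and ER-associated degradation, 7 of 29 were higher and 3 lower (7 and 4 adjusted over the list alone), among them Pdia3 (0.97 ± 0.17, adjusted p = 0.0029) and Manf (0.73 ± 0.13, adjusted p = 0.00251). In the heat shock response 5 of 18 were higher (5, and 1 lower, adjusted over the list alone), led by the mitochondrial chaperonins Hspe1 (1.33 ± 0.23) and Hspd1 (0.96 ± 0.18). Of the p53 targets 3 of 11 were higher (3 adjusted over the list alone), led by the kinase Plk2 (1.55 ± 0.30, adjusted p = 0.00523), and of the ribosomal proteins 3 of 16 (4 adjusted over the list alone). Acinar transcription factors passed as a list without any of 12 members passing, on either adjustment; Gata4 changed by 0.42 ± 0.14 (adjusted p = 0.0687). Among neutrophil and macrophage markers, which had the lower direction, 2 of 21 fell and 1 rose (3 and 1 adjusted over the list alone), with Ngp, a neutrophil granule protein, at -0.74 ± 0.15 (adjusted p = 0.00662). All of these calls except that of the ER chaperones and ER-associated degradation also ended without wild type saline replicate 1 (adjusted p from 0.0643 to 0.159), and that of the ER list ended without wild type saline replicate 2 (adjusted p = 0.108).

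Atf3, a stress-induced transcription factor, averaged 129 in wild type and 92.3 in Mist1KO after saline and did not pass (-0.35 ± 0.46, adjusted p = 0.65). Neither did the ER stress sensors Eif2ak3 (0.50 ± 0.21, adjusted p = 0.128), Ern1 (-0.01 ± 0.26, adjusted p = 0.979) and Atf6 (0.14 ± 0.14, adjusted p = 0.538). In all, 1977 probe sets passed, 1075 higher and 902 lower in Mist1KO. At least 2-fold changes numbered 326 higher and 265 lower. The share of higher calls was 54.4%, and 71.5% when each array was centred on its median. The count dropped to 1068 without Mist1KO saline replicate 3, to 1078 without Mist1KO saline replicate 1 and to 1158 without wild type saline replicate 2. On chromosome 5, which holds Bhlha15, 68 of 587 genes passed (11.6%), against 13.2% of 8880 genes elsewhere (Fisher's exact test, two-sided, p = 0.283), and 12 of 133 within 10 Mb of the gene (9.02%, Fisher's exact test, p = 0.195).

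Caerulein against saline in wild type shows the response of the normal pancreas to the secretagogue. The largest rises were of Rcan1, an inhibitor of the phosphatase calcineurin, 131-fold (7.03 ± 0.63, adjusted p = 4.96e-06), Nfil3, a bZIP transcription factor, 46.1-fold (adjusted p = 1.27e-06), and Fgf21, a stress-induced hormone, 30.3-fold (adjusted p = 1.27e-06). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose 25.2-fold, Egr1, an immediate early transcription factor, 21.9-fold, and Atf3 20.5-fold (4.35 ± 0.46, adjusted p = 1.92e-05). Chac1, which degrades glutathione, and Kel, an endopeptidase, each rose 15.7-fold. Without wild type saline replicate 2, the change of Rcan1 was 7.90.

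The largest falls were of Sostdc1, a secreted antagonist of BMP signalling (15.2-fold, -3.93 ± 0.26, adjusted p = 3.87e-07), Upp2, a uridine phosphorylase (9.47-fold), Reg3g (7.32-fold), Cldn8, a tight junction protein (7.22-fold), Mtss1, a membrane-bending protein (5.77-fold), and Reg3a (5.35-fold). Of the other probe sets of Mtss1, 1 of 2 also fell past the threshold. The immunoglobulin genes Iglv1 (7.04-fold, adjusted p = 0.00373) and Jchain (6.04-fold, adjusted p = 0.00131) were lower too. Their signals after saline varied widely between pancreata, with an SD of 250 on a mean of 274 for Iglv1. Single arrays moved these folds: Iglv1 was at -2.13 without wild type saline replicate 1 and at -3.50 without wild type saline replicate 2, Jchain at -3.19 without the latter, and Reg3g at -3.46 and Reg3a at -3.06 without wild type caerulein replicate 1.

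The integrated stress response and amino acid response moved nearly as a whole: 27 of 29 measured members rose, none fell and 2 did not pass (27 rose and 1 fell adjusted over the list alone). Their mean change was 1.63 (camera adjusted p = 3.38e-31, adjusted p = 0.00442 with an estimated correlation). Examples were Cebpb, a transcription factor (3.60 ± 0.23), Atf4, the factor at the centre of this response (2.24 ± 0.15), Cth, of cysteine synthesis (2.16 ± 0.15), and Slc7a3, an amino acid transporter (2.32 ± 0.16). Of 30 immediate early genes, 21 rose, 1 fell and 8 did not pass (22 and 2 adjusted over the list alone; camera adjusted p = 1.92e-16, adjusted p = 0.0392 with an estimated correlation). Ier3 rose by 3.01 ± 0.28 and Ier2 by 3.27 ± 0.32.

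Keratins and other duct cell markers rose in 5 of 15 members and fell in 1 (6 and 2 adjusted over the list alone; adjusted p = 0.000377, adjusted p = 0.0282 with an estimated correlation). Krt18 rose by 2.85 ± 0.14 and Krt8 by 3.32 ± 0.24, keratins that acinar cells make as well. In the actin cytoskeleton and early epithelial injury list 11 of 20 rose and none fell, also adjusted over the list alone (adjusted p = 6.02e-08, adjusted p = 0.0392 with an estimated correlation). Actg1, a cytoskeletal actin, rose by 2.76 ± 0.18 and Tnfrsf12a, the receptor of the cytokine TWEAK, by 3.73 ± 0.34. The 3′ to 5′ ratio of the related gene Actb was 1.35 ± 0.0643 (SD) after caerulein and 1.53 ± 0.11 after saline. Ribosome biogenesis and nucleolus had 8 of 19 higher and none lower (9 adjusted over the list alone; adjusted p = 6.06e-08, adjusted p = 0.0149 with an estimated correlation), with Nop58 at 1.62 ± 0.23.

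The heat shock response rose in 10 of 18 members and fell in 1 (11 and 2 adjusted over the list alone; adjusted p = 3.95e-06, adjusted p = 0.0757 with an estimated correlation), with Hspa4l at 2.41 ± 0.28 and Hspb8 at 1.46 ± 0.18. Among cell junctions and polarity 7 of 15 rose and none fell (7 and 2 adjusted over the list alone; adjusted p = 0.00425, adjusted p = 0.138 with an estimated correlation), including the gap junction gene Gjb2 (2.83 ± 0.16) and Cdh1, E-cadherin (2.65 ± 0.20). The Reg family secreted stress proteins were lower, with 5 of 7 fallen on both adjustments (camera adjusted p = 0.00425, adjusted p = 0.295 with an estimated correlation). Lower too were fibroblast, stellate cell and matrix markers, which fell in 6 of 19 members (9 adjusted over the list alone; adjusted p = 0.0401, adjusted p = 0.561 with an estimated correlation), with the collagen Col5a1 at -0.72 ± 0.18. That call ended without wild type saline replicate 1, wild type saline replicate 3 or wild type caerulein replicate 2 (adjusted p = 0.0983, 0.175 and 0.104).

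Of the 24 digestive enzymes and secreted acinar proteins, Ctrc alone passed the threshold (-0.69 ± 0.15, adjusted p = 0.00631) on either adjustment, and the list, with a mean of -0.23, did not pass (adjusted p = 0.119). The ER chaperones and ER-associated degradation moved both ways: 2 of 29 rose, the chaperone Hspa5 (1.63 ± 0.11, adjusted p = 5.18e-07) and Herpud1, of ER-associated degradation (1.41 ± 0.21, adjusted p = 0.000371), while 9 fell, with the disulfide isomerase Pdia3 at -1.50 ± 0.17 (2 and 13 adjusted over the list alone; camera adjusted p = 0.119). NF-kB targets, cytokines and chemokines had 3 of 26 higher, led by the receptor Osmr (2.34 ± 0.22), and 3 lower, led by the inhibitor Nfkbia (-0.72 ± 0.12). Their mean was 0.10 and their median -0.15 (adjusted p = 0.718). Oxidative stress genes with metallothioneins had 6 of 17 higher, Gclc and Srxn1 (2.47 ± 0.27) among them, and 3 lower (adjusted p = 0.0888). The circadian clock list had 5 of 9 lower, among them the bZIP factors Tef (-1.11 ± 0.18) and Dbp (-1.15 ± 0.23), and 1 higher, Bhlhe40 (3.02 ± 0.55), with adjusted p = 0.211. Of 12 acinar transcription factors, the nuclear receptor Nr5a2 (-1.41 ± 0.18, adjusted p = 8.2e-05) was among 4 that fell and 1 rose (adjusted p = 0.593). The receptor for the secretagogue itself, Cckar, fell by 1.99 ± 0.16 (adjusted p = 1.88e-06). Lists of islet endocrine (1 of 13 lower, adjusted p = 0.61), endothelial (1 of 10 lower, adjusted p = 0.286) and adipocyte markers (1 of 6 lower, adjusted p = 0.119), cell cycle (none of 15, adjusted p = 0.208) and liver-type secreted proteins (none of 5, adjusted p = 0.596) did not pass.

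Eif2ak3 was higher after caerulein with its brightest probe set, which stands for the gene in all comparisons (0.72 ± 0.21, adjusted p = 0.0253), and with another (1.72 ± 0.37, adjusted p = 0.00556), and not past the threshold with the last (0.90 ± 0.43, adjusted p = 0.17). The probe sets of Ern1 differed, with -0.20 ± 0.26 for the one with the higher mean log2 signal, used elsewhere (adjusted p = 0.63) and 1.33 ± 0.41 for the other (adjusted p = 0.0347). Atf6 fell by 0.54 ± 0.14 (adjusted p = 0.014). In all, 2975 probe sets passed, 1444 higher and 1531 lower after caerulein. At least 2-fold rises numbered 759 and falls 420. The median over all probe sets tested was -0.144, so the balance of directions rests on the scaling: 48.5% of calls were higher as deposited and 67.8% with each array centred on its median. Several calls did not survive every left-out array: Atf6 had adjusted p = 0.0602 without wild type caerulein replicate 3, Eif2ak3 up to 0.106 without wild type saline replicate 2 or 3 or wild type caerulein replicate 2 or 3, and the other probe set of Ern1 0.101, 0.0783 and 0.148 without wild type saline replicate 1, saline replicate 3 or caerulein replicate 2.

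**Figure D3:**
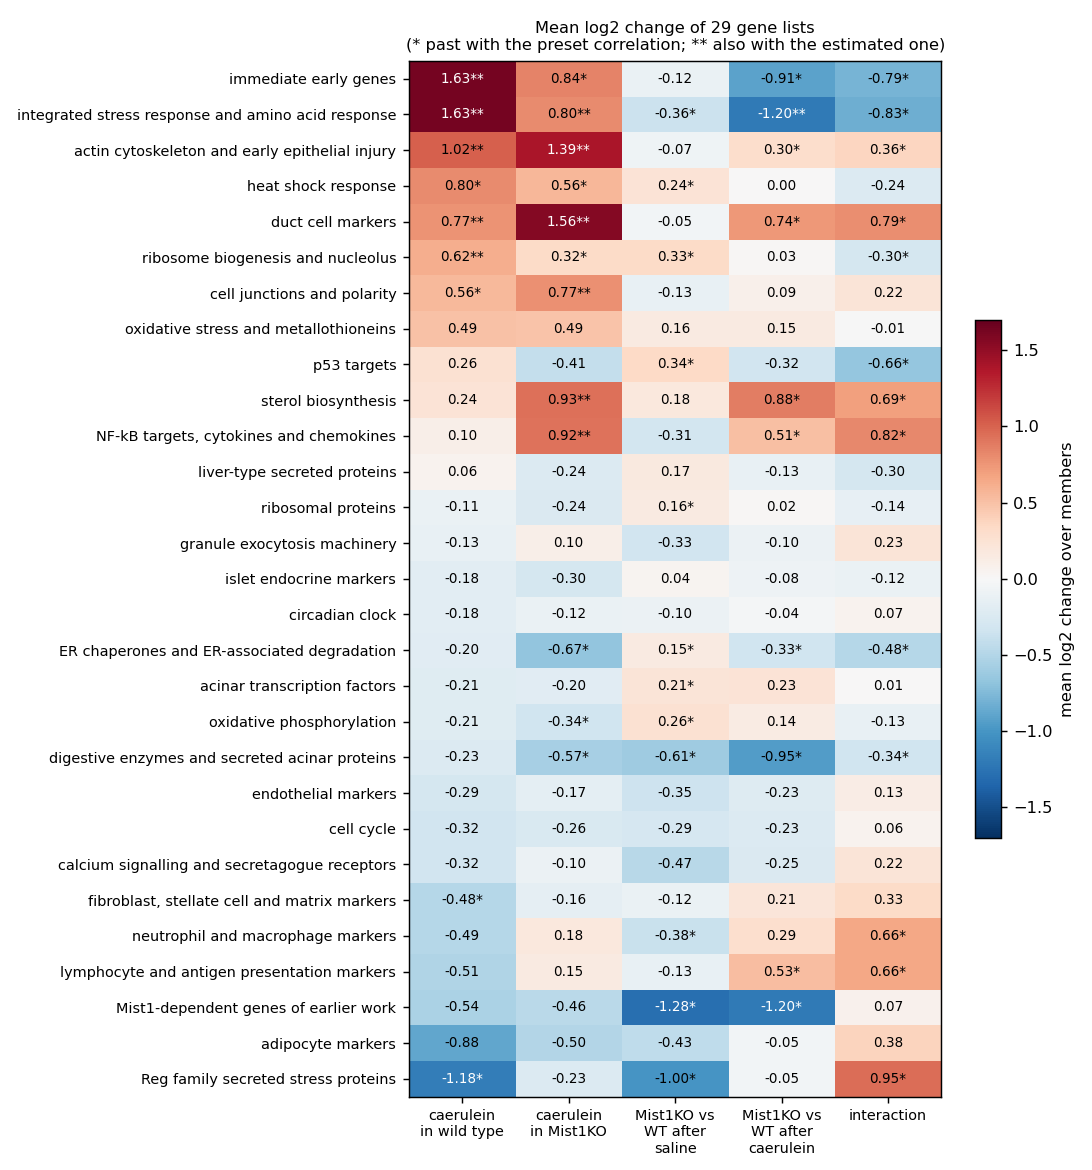
Mean log2 change over the measured members of 29 gene lists in the 4 comparisons and in the interaction, ordered by the change in wild type. The integrated stress response and amino acid response averaged 1.63 in wild type and 0.80 in Mist1KO after caerulein.

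Caerulein against saline in Mist1KO shows the response without Mist1. The genes that rose the most included Rcan1 (49.5-fold, 5.63 ± 0.63, adjusted p = 2.15e-05) and Gclc (30.3-fold, adjusted p = 4.46e-08), as in wild type. They also included Tubb6, a tubulin (19.3-fold), Socs3, a brake on cytokine signalling (12.4-fold, adjusted p = 0.000112), Cldn4, a tight junction protein (12.3-fold), Tnfrsf12a (11.6-fold), Krt19, a duct keratin (11.3-fold, adjusted p = 1.39e-07), and Tax1bp3, a PDZ-domain protein (10.9-fold). Fgf21, which rose 30.3-fold in wild type, averaged 10.5 after saline and 9.63 after caerulein in Mist1KO.

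The largest falls were of Hpgd (21.1-fold, -4.40 ± 0.28, adjusted p = 2e-07), Upp2 (11.4-fold), Nat8, an acetyltransferase (11.1-fold, adjusted p = 4.46e-08), Sesn1, a sestrin (11-fold), Klf15, a metabolic transcription factor (10.6-fold), Mthfd1, of folate metabolism (7.55-fold), Sparc, a matrix protein (6.68-fold, adjusted p = 0.0249), and Lpin1, a phosphatidate phosphatase (6.58-fold). The other probe set of Sparc did not pass, and the call was lost when Mist1KO saline replicate 1 or 2 or Mist1KO caerulein replicate 2 or 3 was left out, with adjusted p = 0.0629, 0.0873, 0.0876 and 0.0822. Without Mist1KO caerulein replicate 3 Cldn4 was at 4.53 and Klf15 at -4.02, and without Mist1KO saline replicate 1 Rcan1 was at 6.27.

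Of 15 duct cell markers, 9 rose and 1 fell (11 and 1 adjusted over the list alone; mean 1.56, camera adjusted p = 2.69e-08, adjusted p = 0.00638 with an estimated correlation). Krt18 rose by 2.86 ± 0.14, Krt8 by 2.88 ± 0.24 and Epcam, an epithelial adhesion protein, by 2.19 ± 0.18. In the actin cytoskeleton and early epithelial injury list 12 of 20 rose and none fell on either adjustment (adjusted p = 4.46e-11, adjusted p = 0.031 with an estimated correlation). Anxa2, an annexin, rose by 2.06 ± 0.12 and Cd44, a hyaluronan receptor, by 2.24 ± 0.21. The 3′ to 5′ ratio of Actb was 1.12 ± 0.0666 (SD) after caerulein and 1.82 ± 0.116 after saline. Cell junctions and polarity had 6 of 15 higher and none lower (7 adjusted over the list alone; adjusted p = 4.04e-06, adjusted p = 0.036 with an estimated correlation), with Gjb2 at 2.93 ± 0.16 and Cdh1 at 2.37 ± 0.20.

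Among NF-kB targets, cytokines and chemokines 10 of 26 rose and none fell on either adjustment (mean 0.92, adjusted p = 2.54e-06, adjusted p = 0.0435 with an estimated correlation). Besides Socs3 they included Osmr (2.47 ± 0.22), the interleukin-4 receptor Il4ra (2.39 ± 0.25, adjusted p = 1.08e-05) and lipocalin Lcn2 (2.58 ± 0.36). Sterol biosynthesis rose in 9 of 13 members with none fallen, on either adjustment (mean 0.93, adjusted p = 3.64e-06, adjusted p = 0.0435 with an estimated correlation), with Hmgcs1 at 2.56 ± 0.19 and Msmo1 at 1.97 ± 0.20. The integrated stress response and amino acid response rose in 18 of 29 members and fell in 1 (19 and 2 adjusted over the list alone; mean 0.80, adjusted p = 4.4e-12, adjusted p = 0.031 with an estimated correlation), with Slc7a3 at 1.87 ± 0.16 and Atf4 at 1.66 ± 0.14. Immediate early genes rose in 12 of 30 and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 8.22e-07, adjusted p = 0.146 with an estimated correlation), with Ier3 at 2.94 ± 0.28. Without Mist1KO caerulein replicate 3, 18 immediate early genes rose and 2 fell.

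ER chaperones and ER-associated degradation fell in 18 of 29 members and rose in 1, on either adjustment (mean -0.67, adjusted p = 4.92e-07, adjusted p = 0.143 with an estimated correlation). Sel1l, of ER-associated degradation, fell by 2.00 ± 0.17 (adjusted p = 2.41e-06), and the oxidase Ero1b changed by -1.60 ± 0.17 and Selenos by -1.25 ± 0.14. The digestive enzymes and secreted acinar proteins fell in 22 of 24 members (23 adjusted over the list alone; mean -0.57, adjusted p = 3.37e-06, adjusted p = 0.459 with an estimated correlation), with the carboxypeptidase Cpb1 at -0.71 ± 0.15 and Ctrc at -0.63 ± 0.15. The hybridisation spikes fell by 1.03 on average in the same comparison. After quantile normalization that list's mean was -0.13 with 6 fallen and 1 risen, and its test did not pass (adjusted p = 0.0982). With each array centred on its median 7 members fell.

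The heat shock response rose in 8 of 18 and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.000403, adjusted p = 0.146 with an estimated correlation), with Hspa4l at 2.83 ± 0.28. Ribosome biogenesis and nucleolus rose in 4 of 19 on either adjustment (adjusted p = 0.00854, adjusted p = 0.143 with an estimated correlation), with the helicase Ddx21 at 1.23 ± 0.20. Oxidative phosphorylation fell in 10 of 28 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.00374, adjusted p = 0.242 with an estimated correlation), with the succinate dehydrogenase subunit Sdhd at -1.30 ± 0.20. Oxidative stress genes and metallothioneins split into 7 higher and 4 lower of 17 (adjusted p = 0.11), with the heme oxygenase Hmox1 at 2.34 ± 0.22 and the transferase Gstm1 at -0.99 ± 0.14. Of fibroblast, stellate cell and matrix markers 3 of 19 fell and 1, the protease inhibitor Timp1, rose (2.78 ± 0.20, list adjusted p = 0.51).

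Atf3 rose 4.97-fold in Mist1KO (2.31 ± 0.46, adjusted p = 0.00221), with signals of 877.7, 871 and 183.8 after caerulein and a change of 3.03 without the last of these arrays. Eif2ak3 changed by 0.36 ± 0.21 with its brightest probe set (adjusted p = 0.237) and rose by 1.93 ± 0.37 with the one that rose by 1.72 in wild type (adjusted p = 0.00182), while the last did not pass (0.95 ± 0.43, adjusted p = 0.135). Ern1 changed by -0.31 ± 0.26 (adjusted p = 0.42), and Atf6 fell by 1.17 ± 0.14 (adjusted p = 3.53e-05). In all, 3764 probe sets passed, 1654 higher and 2110 lower. At least 2-fold rises numbered 819 and falls 606. The median over all probe sets tested was -0.131, and the share of higher calls was 43.9% as deposited and 59.7% with median centring.

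Comparing the genotypes after caerulein shows where the stimulated Mist1KO pancreas stood apart. Fgf21 was 38.8-fold lower in Mist1KO (-5.28 ± 0.38, adjusted p = 8.55e-07), Chac1 10.8-fold lower (adjusted p = 1.16e-05), Nfil3 9.54-fold lower, Cebpb 9.45-fold lower and Sesn2, a stress-induced sestrin, 8.99-fold lower (adjusted p = 5.56e-05). Bhlha15 (11.4-fold), Egf (10.2-fold) and Atp2c2 (9.07-fold) were lower, as after saline. Higher in Mist1KO were Cblif (19.9-fold, 4.31 ± 0.26, adjusted p = 2.51e-07), Smarca1 (12.5-fold), Tm4sf4, a tetraspanin-like protein (9.82-fold), Bex3 (8.56-fold), Rasl10a, a Ras-like GTPase (7.73-fold), Krt20, a keratin (7.11-fold), Fads3, of the fatty acid desaturase family (7.03-fold), and Jchain (6.97-fold, adjusted p = 0.000827).

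The integrated stress response and amino acid response was lower in 26 of 29 members and higher in none, on either adjustment (mean -1.20, camera adjusted p = 2.96e-15, adjusted p = 0.0467 with an estimated correlation). It was the only list of this comparison whose call held with an estimated correlation. Besides Cebpb and Chac1, Cth fell by 1.74 ± 0.15 (adjusted p = 4.24e-06) and Slc3a2, an amino acid transporter chain, by 1.22 ± 0.12. Immediate early genes were lower in 15 of 30 and higher in none (16 adjusted over the list alone; adjusted p = 7.92e-05, adjusted p = 0.376 with an estimated correlation), with Ier2 at -2.10 ± 0.32 and the nuclear receptor Nr4a2 at -1.10 ± 0.17. Of ER chaperones and ER-associated degradation 11 of 29 were lower and 5 higher (15 and 5 adjusted over the list alone; adjusted p = 0.0473, adjusted p = 0.59 with an estimated correlation), with Herpud1 at -3.03 ± 0.21 and Ero1b at -1.54 ± 0.17. That list's call ended with median centring (adjusted p = 0.0585) and without wild type caerulein replicate 2 (adjusted p = 0.223), among other single arrays.

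All 24 digestive enzymes and secreted acinar proteins were lower in Mist1KO, also adjusted over the list alone (mean -0.95, adjusted p = 5.37e-14, adjusted p = 0.376 with an estimated correlation). Ctrc fell by 2.06 ± 0.15 (adjusted p = 1.16e-06), the phospholipase Pla2g1b by 1.20 ± 0.15 and Amy1 by 1.54 ± 0.22. The 18 probe sets of the hybridisation spikes fell by 1.23 on average, and 24 other genes of matched brightness by 0.46. With quantile normalization the list's mean was -0.27, 5 members fell and its test still passed (adjusted p = 0.0177). The Mist1-dependent genes of earlier work fell in 6 of 9 and rose in 2, on either adjustment (adjusted p = 0.00561, adjusted p = 0.0912 with an estimated correlation), with Rab3d at -2.48 ± 0.12.

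Higher in Mist1KO were sterol biosynthesis (8 of 13, 8 and 1 lower adjusted over the list alone; adjusted p = 7.39e-06, adjusted p = 0.0912 with an estimated correlation), with Hmgcs1 at 2.41 ± 0.19 and Idi1 at 2.18 ± 0.25, and duct cell markers (6 of 15, 7 and 1 lower adjusted over the list alone; adjusted p = 0.0113, adjusted p = 0.0912 with an estimated correlation), with Epcam at 1.63 ± 0.18 and Cldn7 at 1.52 ± 0.17. NF-kB targets, cytokines and chemokines were higher in 7 of 26 and lower in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.000787, adjusted p = 0.182 with an estimated correlation), with Nfkbia at 0.90 ± 0.12 and Il4ra at 1.85 ± 0.25. Lymphocyte and antigen presentation markers were higher in 2 of 13 and lower in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0451, adjusted p = 0.58 with an estimated correlation), led by the immunoglobulin gene Ighm (2.59 ± 0.53, adjusted p = 0.00356; 1.94 without wild type caerulein replicate 2). Actin cytoskeleton and early epithelial injury was higher in 5 of 20 and lower in 3 on either adjustment (adjusted p = 0.0485, adjusted p = 0.519 with an estimated correlation), with Anxa2 at 1.91 ± 0.12. The lymphocyte list's call ended without Mist1KO caerulein replicate 3 (adjusted p = 0.116) and the actin list's without wild type caerulein replicate 1 (adjusted p = 0.164). Without Mist1KO caerulein replicate 3, sterol biosynthesis had 5 members higher and 1 lower, and its list test still passed (camera adjusted p = 0.000146).

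Atf3 was 5.27-fold lower in Mist1KO after caerulein (-2.40 ± 0.46, adjusted p = 0.00235; -1.68 without Mist1KO caerulein replicate 3) and Atf6 1.4-fold lower (-0.48 ± 0.14, adjusted p = 0.0247). The call of Atf6 ended with median centring (adjusted p = 0.0526), without wild type caerulein replicate 1 or 2 (adjusted p = 0.0902 and 0.0882) and without Mist1KO caerulein replicate 1 or 2 (adjusted p = 0.0612 and 0.0754). Eif2ak3 (0.14 ± 0.21, adjusted p = 0.681) and Ern1 (-0.13 ± 0.26, adjusted p = 0.76) did not pass. In all, 3177 probe sets passed, 1579 higher and 1598 lower. At least 2-fold changes numbered 526 higher and 476 lower. The share of higher calls was 49.7%, and 61.7% with median centring. On chromosome 5, 122 of 587 genes passed (20.8%), against 20.7% elsewhere (Fisher's exact test, two-sided, p = 0.958). The genotypes differed in the same direction after both injections on 487 probe sets that were higher and 466 that were lower in Mist1KO, where independent lists would share 108 and 91.7.

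The interaction of genotype and injection tests whether the response to caerulein itself differed between the genotypes. It is the caerulein change in Mist1KO minus that in wild type. Fgf21 had the largest negative value (-4.96 ± 0.53, adjusted p = 0.000466), since it rose in wild type alone. Herpud1 rose in wild type and fell in Mist1KO (-3.13 ± 0.30, adjusted p = 0.000243), from a mean signal of 2898 to 7472 and from 3018 to 908. Nat8 was steady in wild type, at 224 and 220, and fell in Mist1KO (-3.46 ± 0.25, adjusted p = 2.26e-05). Nfil3 (-3.10 ± 0.60, adjusted p = 0.0141) rose less in Mist1KO, and Sesn2 (-3.07 ± 0.52, adjusted p = 0.00622) rose in wild type and did not pass in Mist1KO. The largest positive values belonged to Iglv1 (5.05 ± 0.82, adjusted p = 0.00495), Jchain (3.94 ± 0.65, adjusted p = 0.0057), Reg3g (3.85 ± 0.79, adjusted p = 0.0176), Ighm (3.52 ± 0.75, adjusted p = 0.0209) and Igkv8-30 (2.89 ± 0.70, adjusted p = 0.0406). The 5 other tested probe sets of Ighm pointed the same way, and only 1 of them passed. Without wild type caerulein replicate 2 Ighm was at 2.87 and Igkv8-30 at 2.15, without wild type saline replicate 2 Iglv1 was at 5.73 and Jchain at 4.54, without wild type saline replicate 1 Iglv1 was at 4.37, and without wild type caerulein replicate 1 Reg3g was at 4.44.

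**Figure D4:**
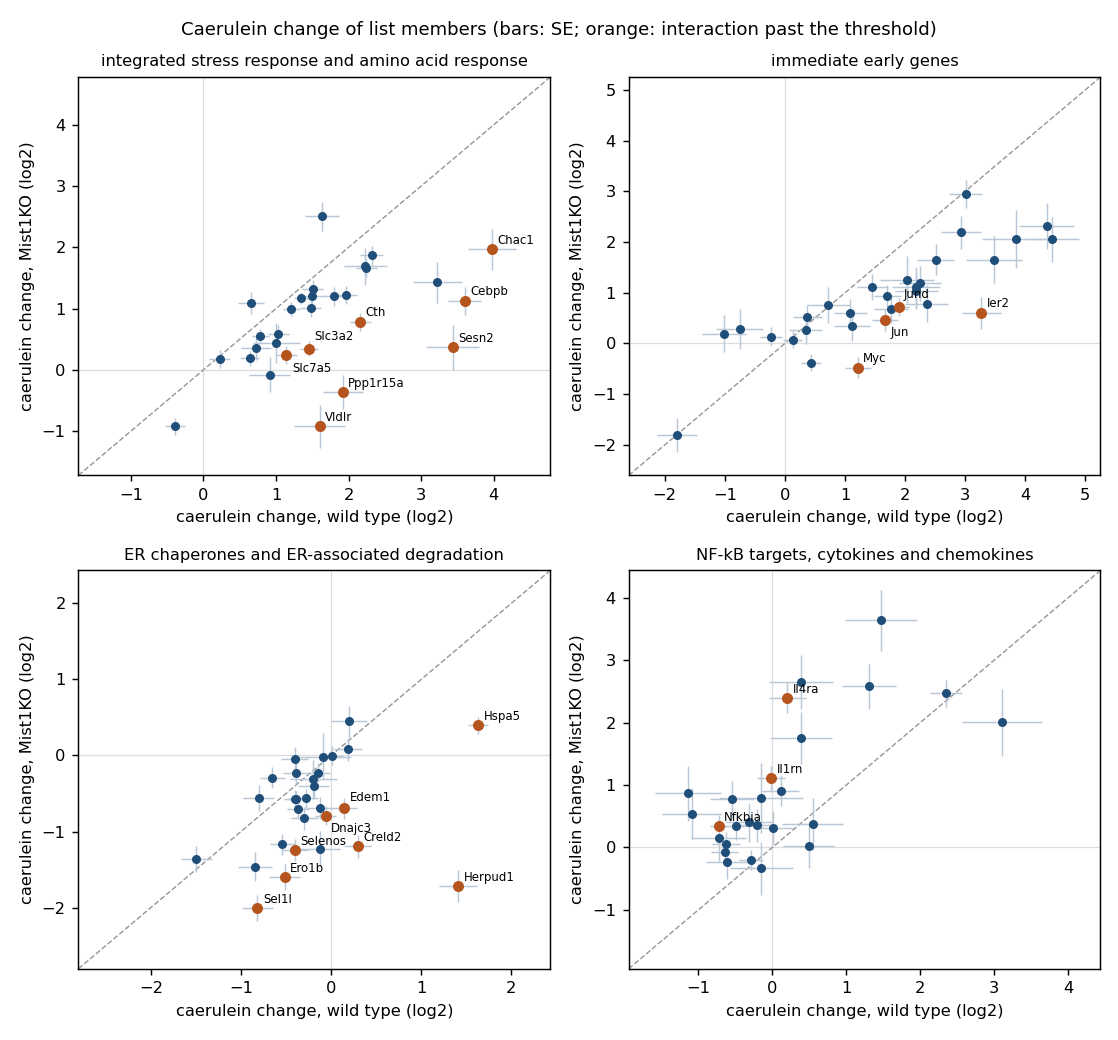
Caerulein change in wild type against that in Mist1KO, on log2 scales, for the members of 4 gene lists, with bars of 1 SE. Orange points are members whose interaction passed, such as Herpud1 with -3.13 and Il4ra with 2.19, and the dashed line marks equal change.

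All lists that passed did so only with the preset correlation: of 29, 13 passed with it and none with the estimated one. The integrated stress response and amino acid response had the smallest p: 8 of 29 members had a negative interaction and none a positive one (15 and 1 adjusted over the list alone; mean -0.83, camera adjusted p = 6.2e-11, adjusted p = 0.0677 with an estimated correlation). They included Cebpb (-2.47 ± 0.32, adjusted p = 0.00168), Cth (-1.37 ± 0.21) and Slc3a2 (-1.11 ± 0.17). ER chaperones and ER-associated degradation had a negative interaction in 8 of 29 (11 adjusted over the list alone; adjusted p = 2.75e-06, adjusted p = 0.19 with an estimated correlation), among them Hspa5 (-1.24 ± 0.16, adjusted p = 0.00155) and Creld2 (-1.49 ± 0.21). Immediate early genes had it in 4 of 30 (10 adjusted over the list alone; adjusted p = 6.35e-06, adjusted p = 0.205 with an estimated correlation), among them Ier2 (-2.67 ± 0.45) and Myc (-1.69 ± 0.30). The p53 targets had it in 2 of 11 (5 adjusted over the list alone; adjusted p = 0.012, adjusted p = 0.103 with an estimated correlation), led by Trp53inp1 (-2.92 ± 0.55; -2.31 without Mist1KO caerulein replicate 3). The digestive enzymes and secreted acinar proteins (none of 24, 1 lower adjusted over the list alone) and ribosome biogenesis and nucleolus (none of 19, 1 lower adjusted over the list alone) passed as lists, with adjusted p = 0.000265 and 0.00936, and adjusted p = 0.542 and 0.161 with an estimated correlation. The nearest members were Amy1 (-1.20 ± 0.32, adjusted p = 0.0558) and Wdr43 (-0.71 ± 0.19, adjusted p = 0.0588). After quantile normalization the enzyme list did not pass (adjusted p = 0.161).

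A positive interaction was seen in NF-kB targets, cytokines and chemokines (3 of 26, 8 adjusted over the list alone; adjusted p = 8.8e-07, adjusted p = 0.0677 with an estimated correlation), with Nfkbia at 1.06 ± 0.16 and Il4ra at 2.19 ± 0.35. With this probe set Nfkbia fell in wild type and rose in Mist1KO (0.34 ± 0.12, adjusted p = 0.049 in Mist1KO), while its 3 others did not pass in Mist1KO or in the interaction. Sterol biosynthesis had 4 of 13 (5 adjusted over the list alone; adjusted p = 2.26e-05, adjusted p = 0.0741 with an estimated correlation), with Hmgcs1 at 1.75 ± 0.27 and Idi1 at 1.83 ± 0.36, and duct cell markers had 2 of 15 (3 adjusted over the list alone; adjusted p = 0.00274, adjusted p = 0.0677 with an estimated correlation), led by Krt19 (1.62 ± 0.30, adjusted p = 0.0113). Neutrophil and macrophage markers (1 of 21, 3 adjusted over the list alone; adjusted p = 0.000167, adjusted p = 0.296 with an estimated correlation) were led by the receptor Cd14 (1.66 ± 0.35, adjusted p = 0.0206; from 0.0508 to 0.0559 without Mist1KO saline replicate 1 or 3 or Mist1KO caerulein replicate 2), and lymphocyte and antigen presentation markers (1 of 13, 4 adjusted over the list alone; adjusted p = 0.00462, adjusted p = 0.349 with an estimated correlation) by Ighm. Neither of these lists passed with caerulein in wild type or in Mist1KO. Actin cytoskeleton and early epithelial injury had 2 of 20 higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.026, adjusted p = 0.349 with an estimated correlation), with Anxa2 at 1.17 ± 0.18 and Actg1 at -1.45 ± 0.26. That call ended with the stricter filter (adjusted p = 0.108), with the mean of all probe sets of a gene (adjusted p = 0.129) and when any 1 of 5 arrays was left out (adjusted p from 0.0515 to 0.122). The Reg family secreted stress proteins, which fell in wild type and did not pass as a list in Mist1KO, had Reg3g alone of 7 (3 adjusted over the list alone; adjusted p = 0.0423, adjusted p = 0.397 with an estimated correlation), and the call of the Reg family secreted stress proteins ended when any 1 of 5 arrays was left out (adjusted p from 0.0612 to 0.188, the highest without Mist1KO caerulein replicate 3).

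The difference between the genotypes in the caerulein response was not past the threshold for Atf3 (-2.04 ± 0.65, adjusted p = 0.114; -1.33 without Mist1KO caerulein replicate 3), Atf6 (-0.62 ± 0.20, adjusted p = 0.11), Eif2ak3 (-0.36 ± 0.29, adjusted p = 0.598), Ern1 (-0.12 ± 0.36, adjusted p = 0.919) or Bhlha15 itself (0.30 ± 0.25, adjusted p = 0.604). In all, 518 probe sets passed, 238 with a positive and 280 with a negative interaction, and 2630 had an unadjusted p under 0.05. Caerulein moved 882 probe sets up and 720 down in both genotypes, where independent lists would share 152 and 205.5. It moved 21 probe sets up in wild type and down in Mist1KO, and 14 the other way. The interaction passed for each of these, as it had to once both changes passed in opposite directions in the same fit. Over 9481 genes, which are not independent replicates, the change in wild type and that in Mist1KO had a Pearson correlation of 0.615 and a Spearman correlation of 0.496, and 71.6% of genes had the same sign in both. The interaction count dropped to between 271 and 344 when Mist1KO caerulein replicate 1 or 2, Mist1KO saline replicate 1 or 3 or wild type caerulein replicate 2 was left out. It was 328 without the intensity trend.

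**Figure D5:**
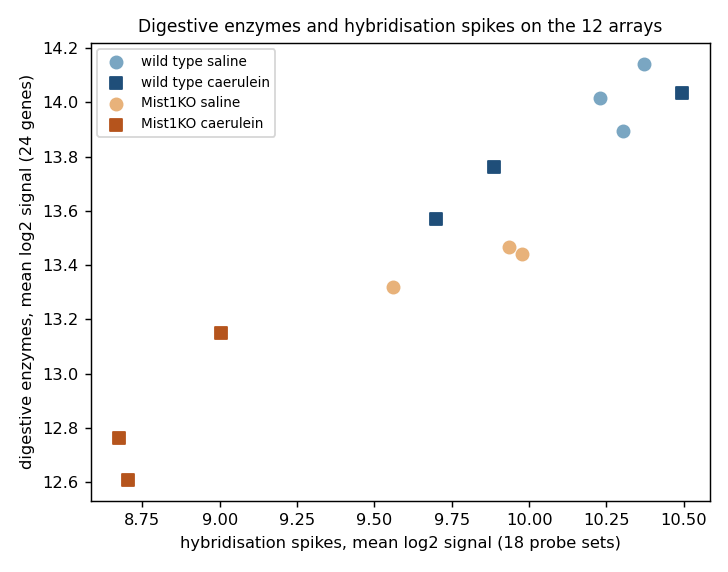
Mean log2 signal of the 24 digestive enzymes and secreted acinar proteins against that of the 18 probe sets of hybridisation spikes, 1 point per array. Both were lowest on the 3 arrays of Mist1KO after caerulein, whose spikes had a geometric mean signal of 446.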

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

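What drew attention here was a tested difference between the genotypes in their change with caerulein, the interaction, and the log2 values of this paragraph and the next are the caerulein change in Mist1KO minus that in wild type. It passed the threshold for 518 probe sets. Named genes with a positive value were Iglv1 (5.052), Jchain (3.945), Reg3g (3.85), Ighm (3.524) and Igkv8-30 (2.893), whose mean signals fell in wild type and rose in Mist1KO. Those with a negative value were Fgf21 (-4.961), Nat8 (-3.464), Herpud1 (-3.127), Nfil3 (-3.1) and Sesn2 (-3.067). Of these, Herpud1 rose in wild type and fell in Mist1KO. The call of Nfil3 ended without an offset (adjusted p = 0.141). Reg3g ended without Mist1KO saline replicate 3 (adjusted p = 0.0508), and Ighm without that array (adjusted p = 0.0612) or without Mist1KO saline replicate 1 (adjusted p = 0.056). Igkv8-30 had adjusted p-values between 0.0578 and 0.102 without several single arrays.

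The lists with a tested difference of means, with the preset correlation, were the integrated stress response and amino acid response (-0.831), immediate early genes (-0.79), p53 targets (-0.664), ER chaperones and ER-associated degradation (-0.48), digestive enzymes and secreted acinar proteins (-0.342), and ribosome biogenesis and nucleolus (-0.303). In the other direction were the Reg family secreted stress proteins (0.953), NF-kB targets, cytokines and chemokines (0.821), duct cell markers (0.791), sterol biosynthesis (0.693), neutrophil and macrophage markers (0.662), lymphocyte and antigen presentation markers (0.658), and actin cytoskeleton and early epithelial injury (0.364). Of these 13 lists, 0 passed with an estimated correlation.

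Of the tests below, the regroupings of arrays and the chromosome test were fixed before the data were examined, and the 7 tests of the digestive enzymes, of the stress response and of the immunoglobulin genes were chosen after the results were seen. The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. In each of the 4 comparisons 1 of 10 splits, the real one, had as many probe sets past the threshold, and the highest other splits had 1, 0, 3 and 1, against 2975, 3764, 1977 and 3177. Each of the other splits mixes the groups compared, so any real difference adds to the spread and lowers the calls. The gap in counts is therefore no measure of chance. For the interaction, 6 of 100 regroupings of genotype within each injection had at least 518 calls, the highest other with 4445. That is not a share under 0.05, so by the rule fixed beforehand the real count was not set apart from those of the regroupings. Sorting the regroupings by whether they kept the genotypes apart was not part of that rule. The regrouping with 4445 calls mirrored the genotypes in one injection and so carried the genotype difference itself. The other 4 came from 23 regroupings that kept the genotypes apart in a single injection, and these carried the genotype difference too. The 75 that mixed the genotypes in both injections had at most 1 call, but mixing adds any real genotype difference to the spread and so lowers the calls. The regroupings therefore cannot decide whether 518 calls could come from the grouping alone. Of the genes differing between the genotypes after saline, 5.48% lay on the chromosome of Bhlha15. With 587 tested genes there and 1172 calls elsewhere that share had to be small, so it decides nothing. On that chromosome 11.6% of genes passed, and 9.02% within 10 Mb of Bhlha15, against 13.2% on the other chromosomes. This argues against alleles around Bhlha15 that act on genes near them as the main source. Alleles elsewhere in the genome, and effects on distant genes, were not tested.

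All 24 digestive enzymes and secreted acinar proteins were lower in Mist1KO than in wild type after caerulein, together with the hybridisation spikes. Within groups, the mean of the enzymes followed that of the spikes over the 12 arrays (Pearson correlation 0.815, exact permutation p = 0.00926; Spearman correlation 0.797), and without the 2 arrays farthest out it was 0.882. A smaller acinar share of the tissue would raise markers of islets, endothelium and fibroblasts, whose median change was -0.073 over 42 genes. Duct cell markers and lymphocyte and antigen presentation markers were outside that set. With the preset correlation both passed as higher lists in the same comparison, so the markers do not settle the acinar share. Given the correlation with the spikes, the fall of the list may come in part from array scale and a ceiling on the brightest probe sets. A lower enzyme content or a smaller acinar share could not be told apart from it.

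The integrated stress response and amino acid response rose less with caerulein in Mist1KO. Without Mist1KO caerulein replicate 3, its mean against wild type after caerulein was -1.086, with 23 members lower, against -1.196 with all arrays. Its mean interaction without that array was -0.727, against -0.831 with all arrays. Among 10000 random sets of genes with matched wild type changes, 0.67% had a lower mean interaction than -0.831. Those sets averaged -0.481, a mean that the matching on the measured wild type change itself pulls below 0, and they ignore the correlation between genes. With the scaling that left the smallest size the mean was -0.769. These values argue against the weak array and the scaling as technical explanations alone. A weaker response of all induced genes, which would be biological, could give part of the difference. Whether it gives all of it could not be decided, since the random sets ignore the correlation between genes. A weaker stress response in the absence of Mist1 may remain, although with an estimated correlation the list had adjusted p = 0.0677.

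The immunoglobulin genes Iglv1, Jchain, Ighm and Igkv8-30 had a mean interaction of 3.854. The other 12 members of the lymphocyte list averaged 0.419. The 4 genes had been named for their large interactions, which favours a lower mean in the others. The comparison therefore cannot decide whether lymphoid tissue was carried along with some pancreata. Within groups the 4 genes varied together from pancreas to pancreas, with a mean pairwise correlation of 0.76, above 100% of 2000 random sets of genes. Plasma cell content that differs between single pancreata could thus give such a difference with 3 pancreata per group, without any effect of genotype. An effect of genotype could not be told apart from it.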

How the results depend on the processing

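None of the 56 list calls changed direction under the alternatives run for it. No named gene did where it passed in the main fit or in the alternative. Genes that passed in neither were not checked. The correlation of the caerulein changes kept its direction with no filter, the stricter filter, quantile normalization and each array left out. The share of higher calls crossed 50% in several alternatives. For caerulein in wild type it was 48.5%, and 67.8% with median centring, 52.2% with quantile normalization, 57.2% with only the 2 groups compared, 64.4% with the 2-fold threshold and 47.5% to 54.3% with an array left out. For caerulein in Mist1KO it was 43.9%, and 59.7% with median centring and 57.5% with the 2-fold threshold. For the genotypes after caerulein it was 49.7%, and in the same order 61.7%, 53.8%, 50.7%, 52.5% and 48% to 51.4%, with 51% without filter and 50.5% with the replicate block. With quantile normalization 4 lists passed for Mist1KO against wild type after saline. With the stricter filter 7 lists passed there and 5 for the genotypes after caerulein, and the correlation of the caerulein changes was 0.697. Without the intensity trend 328 probe sets passed in the interaction. Asking also for a 2-fold change left 1179, 1425, 591 and 1002 probe sets in the 4 comparisons, by construction. With the correlation estimated in camera 5, 6, 0, 1 and 0 lists passed in the 4 comparisons and the interaction. With each array left out in turn, which by construction leaves fewer arrays, between 1068 and 2059 probe sets passed for the genotypes after saline and between 271 and 552 in the interaction, and 8 to 15 lists passed for caerulein in wild type and 7 to 12 for the genotypes after saline. Otherwise the cause was not tested. Of 56 list calls, 1 ended with the smaller offset and 1 without offset, 10 with quantile normalization, 3 with median centring, 3 without filter, 13 with the stricter filter, 7 without the trend, 7 with the mean of all probe sets of a gene, 44 with the estimated correlation and 12 when the arrays were left out in turn. Only the 2 groups compared ended 3 of 43. Of 264 gene calls, 14 ended with quantile normalization, 6 with median centring, 14 without filter, 16 without the trend and 36 when the arrays were left out in turn. The replicate number as a block gave 2772, 3536, 1648, 2903 and 392 probe sets and ended 4 list and 8 gene calls. Arrays of the same number in different groups had correlations of their residuals between -0.104 and 0.045, and those of different numbers between -0.057 and 0.093, so the numbers were not treated as pairs. How far dim genes lie above background could not be read from the values.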

Other observations

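The fixed list of oxidative stress genes and metallothioneins did not pass with caerulein in wild type (6 of 17 rose and 3 fell, adjusted p = 0.0888) or in Mist1KO (7 rose and 4 fell, adjusted p = 0.11). Single members rose in both genotypes, chosen here after their values were seen. Gclc rose by 4.66 ± 0.25 in wild type and 4.92 ± 0.25 in Mist1KO, Srxn1 by 2.47 ± 0.27 and 2.64 ± 0.27, and Hmox1 by 1.49 ± 0.22 and 2.34 ± 0.22. The transferase Gstm1 was higher in Mist1KO than in wild type after saline (1.71 ± 0.14, adjusted p = 4.92e-06) and after caerulein (1.42 ± 0.14).

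Further genes, also chosen after their values were seen, had a caerulein change that differed between the genotypes. Timp1, an inhibitor of matrix proteases, had an interaction of 2.73 (adjusted p = 0.000406), Orai1, a calcium channel of the plasma membrane, of 1.28 (adjusted p = 0.00369), and Nr5a2, an acinar nuclear receptor, of 1.42 (adjusted p = 0.00749). Klf9, a transcription factor, rose by 1.06 in wild type and changed by -1.05 in Mist1KO with its most changed probe set, and 1 other of its 7 probe sets passed in opposite directions as well.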
